A study of Oryza sativa with 104 samples.

How the data were processed

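Total RNA from single leaves of field-grown rice was measured on 2-colour Agilent oligonucleotide arrays. Per the labels, leaves were cut in the paddy field every 2 h and frozen in liquid nitrogen, RNA was extracted with a column kit and amplified to labelled cRNA by T7 RNA polymerase, with Cy3 for the wild-type cultivar Norin 8 and Cy5 for the osgi mutant. No array had the dyes swapped. Each of the 104 arrays held 1 leaf of each genotype, of the same hour and stage, and the groups were the 13 time points, each with 2 individual plants of each of 4 stages (transplanting dates). The array labelled st4_n2 at 19:00 on the first day was left out, because the submitters stated that they used its Cy3 channel only.

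The scanned spot intensities, as mean signal and median local background of each channel, were deposited without normalization. Per the file headers, Agilent Feature Extraction 9.5.3.1 had quantified the spots, and processed signals in intensity units had been made from them by spatial detrending, background subtraction and a linear and LOWESS dye normalization. The deposited log10 ratio of Cy5 over Cy3, per the file headers, was taken from those processed signals. The deposited flags mark spots well above background, saturated or outlying, as 0 or 1. The authors' series matrix copied the log10 ratio for 103 arrays (all values equal within 1e-04), with column medians from -0.0021 to 0, so that its scale, centring and direction are known. Its column for the array left out held the Cy3 processed signal instead, with a median of 640, and was not used.

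Analyses were run in R 4.3.3 with limma 3.58.1. Backgrounds were corrected by normexp with an offset of 50, the log2 ratio M of osgi over Norin 8 was normalized by loess within each array with control spots at weight 0, and spots flagged as outliers were removed. Spots of one probe were averaged. For levels in one genotype, average intensities were then quantile normalized between arrays (Aquantile) and the channels separated. A probe was tested if it lay well above background in either channel on at least 8 arrays and had at least 2 values at each time point. This left 37278 of 42477 probes, for 25751 genes. A gene with several probes was represented by the one with the highest mean log2 signal.

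In the files 41908 of the 42477 probes carry a locus, and most a description. None of the 29690 loci and none of the 40853 probe accessions was found in the reference gene table of another assembly, so the names in the files were kept and no coordinates are given. Symbols of list genes were assigned to loci from general knowledge of rice genes before the data were examined and were not checked against a gene table, so every list count rests on this assignment. The 20 lists hold 212 genes, of which 196 were tested, and 1 chlorophyll gene was left out because the files describe its locus as a transcription factor.

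A single limma fit of M with time point (13 levels) and stage (4 levels, summing to zero) gave the mean over the day, the difference at each time point, and F tests over time points and over stages. Rhythms were fitted as a cosine of 24 h with stage as covariate, in each genotype and in M, and tested by limma's F test. The amplitude ratio and the shift of the peak were computed for 6708 genes rhythmic in the mean of both channels. Peaks are given as clock hours. Stage 1 was compared with stage 4, and the second 7:00 with the first, in single genotypes. P-values were adjusted by Benjamini and Hochberg over all tested probes, within a time point for the hourly comparisons. A gene was called at an adjusted p under 0.05 and at least 2-fold, and for F tests a range or peak to trough of at least 1 (log2). Lists were tested as sets on the mean ratio by camera with a preset correlation of 0.01, with an estimated correlation, and by fry, adjusted over the 18 lists tested as sets. Fry asks only whether the genes of a list move one way on balance.

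The design, the gene lists, the alternatives other than those named as added, and the rule for named genes were fixed before the data were examined. By that rule OsGI comes first, followed in each comparison by up to 4 members of each list with the largest effect, with any clock or flowering gene allowed, and by the 6 highest and 6 lowest called genes (the 10 with the largest range for F tests). The latter needed a description and the same sign in each of the 4 stages. Genes described as hypothetical proteins, without a hit or as non-coding counted as undescribed. The same sign was read from stage means for the mean and the mornings, at the hour of largest difference for single hours, and from a positive relation of the stage's time profile or cosine to that of all arrays for the time and rhythm tests. For the stage tests, both plant numbers had to share the sign. These readings for the F tests and the stage tests were settled after the data were seen. Fewer genes than the rule allows are named in the text, the values of 1 gene are not reported here, and the singled-out genes at 2 levels in osgi were chosen after their values were seen.

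Where a probe was not well above background on any array of a genotype at an hour, only a bound was computed, against the higher of the probe's own signal and the lowest signal among probes well above background on each array. Of 239 named genes none had a saturated spot.

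Each test was tested on simulated data of 10000 genes, 200 of them changed. Changes of 1.5 (log2) were recovered for 100% of genes in the mean over the day, 95% at single time points, 88% across time points, 100% across stages, 100% for the rhythm in Norin 8, in osgi and of the difference, 99% for the stages in Norin 8 and in osgi, and 98% between the mornings. At most 3 unchanged genes were called in any of these tests. The simulated noise was independent between arrays, without slide or scan batch effects, so these rates need not hold for the real arrays. For the rhythm difference a true amplitude of 75% and a shift of 1 h were read as 74.9% and 0.988 h over 200 genes. All 200 had the same large peak to trough, so this says little about weak rhythms. The simulations were written after the first runs on the real arrays.

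Median net signal per array was 206 to 515 in Norin 8 (median 344) and 407 to 1157 in osgi (median 670). Over 51 pairs of arrays of the same stage and hour, M correlated across genes by 0.214 to 0.843 (median 0.676), and no pair was near identical, the smallest SD of a difference being 0.21 (log2, Norin 8). The 26 slides and 13 scan batches followed the time points, with 2 slides and 1 scan batch for each, stages 1 and 2 on one slide and stages 3 and 4 on the other.

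Alternatives were no background subtraction, an offset of 1 (added after seeing the data), Agilent's processed signals (for one channel minus the array's 75th percentile), the series matrix values, median centring in place of loess, loess without scaling between arrays, no filter and a filter on at least 50% of arrays, the left-out array included, each plant label left out, plant label as a block, slide as a random block, a 1.5-fold threshold, means of each stage and hour, a second harmonic of 12 h, an F test over time points for rhythms, no second 7:00, the other probes of a named gene, all probes of a gene, an estimated correlation or fry for the lists, and, added after seeing the data, no 13:00, neither 11:00 nor 13:00, or no 3:00.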

Results

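Leaves of rice plants growing in a paddy field were collected every 2 h over 24 h, from 7:00 on one August morning to 7:00 on the next, and their transcripts were measured on 2-colour oligonucleotide arrays. Each array compared a leaf of the wild-type cultivar Norin 8, labelled with Cy3, with a leaf of the osgi mutant, labelled with Cy5. The osgi plants carry a mutation in OsGI (Os01g0182600), the rice counterpart of GIGANTEA, a plant protein of the circadian clock and of photoperiodic flowering. Plants had been transplanted on June 6, 13, 20 or 27, so that 4 developmental stages (stage 1 the earliest transplanted) were sampled at the same hours. With 2 individual plants per stage this gave 8 arrays at each of 13 time points, 104 in all, of which 103 were used. On these arrays a median of 74.2% of probes in the Norin 8 channel (range 52.2 to 80.4%) and 78.8% in the osgi channel (72.2 to 85.1%) lay well above background, and 25751 genes were tested. The number of arrays limits the precision of every value.

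OsGI mRNA was lower in the leaf labelled osgi on each of the 103 arrays. Averaged over the day, the brightest OsGI probe read 5.23-fold lower in osgi than in Norin 8 (log2 ratio -2.39 ± 0.017 SE, n = 103, limma adjusted p = 1.69e-103). The second probe of OsGI read 7.52-fold lower, and all 3 other probes read lower on 103 of 103 arrays each. The last pair were well above background in osgi on only 77 and 80 arrays, and on none at 3:00 and 5:00, so no fold over the day is given for them. At 17:00, where all 8 osgi leaves had them well above background, they read 249.9- and 75.4-fold lower. The reduction of the brightest probe ran from 2.24-fold at 5:00 (log2 ratio -1.17 ± 0.20 SD, n = 8) to 8.71-fold at 17:00 (-3.12 ± 0.21 SD, n = 8). The remaining OsGI signal in osgi still cycled, with a peak at 16.4 h and a peak to trough of 5.67 (log2), against 16 h and 7.05 in Norin 8. On the other 3 probes its peak to trough in osgi read 5.09, 3.18 and 4.02, against 6.55, 6.71 and 7.06 in Norin 8, where the last pair were not well above background in osgi at 3:00 and 5:00. The peaks of these 3 probes read 15.6, 14.95 and 15.3 h in osgi, against 15.7, 15.5 and 15.4 h in Norin 8. A later OsGI peak in osgi was thus read on the brightest probe alone. The labels do not give the lesion, so whether a probe lies inside it is not known here.

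**Figure D1:**
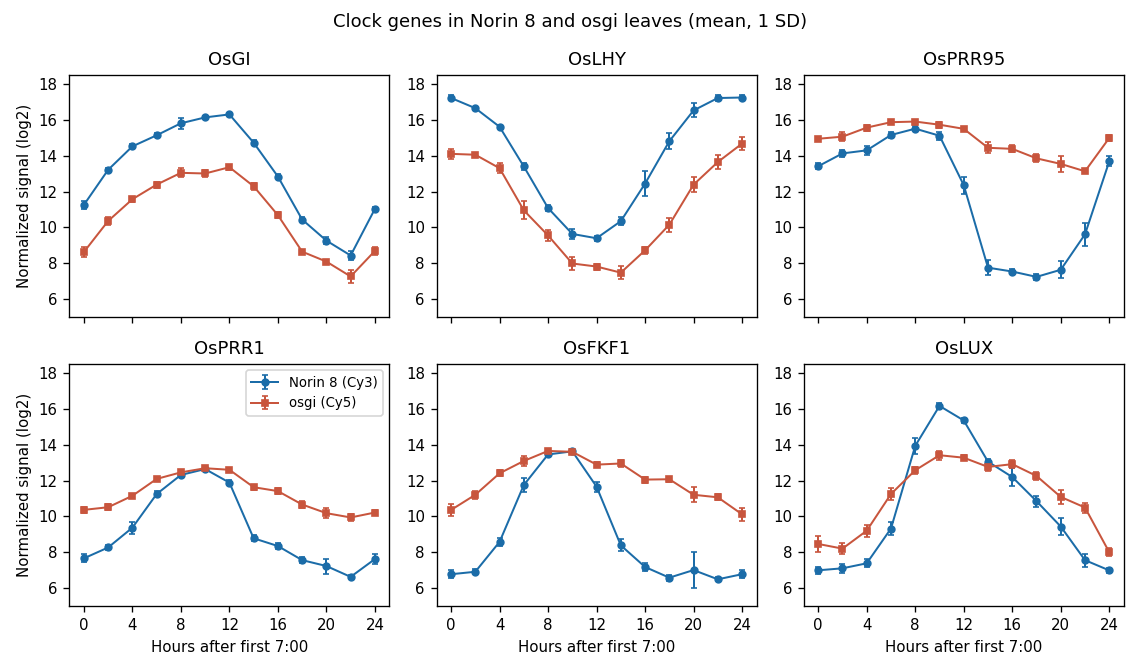
Mean log2 signal of 6 clock genes in Norin 8 (Cy3) and osgi (Cy5) leaves against hours after the first 7:00, with bars of 1 SD over 8 leaves (7 at 19:00). OsGI lay below Norin 8 at all 13 time points, and the OsPRR95 rhythm had a peak to trough of 2.36 (log2) in osgi against 8.87 in Norin 8.

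The first comparison asked which genes differed between the genotypes in the mean over the 24 h. Several clock genes did. OsFKF1 (Os11g0547000), an F-box blue-light receptor, was called higher in osgi (limma adjusted p = 5.76e-80), but only 57 of the 103 Norin 8 leaves had its brightest probe well above background, and none at 5 of the 13 time points, so no fold over the day is given. Over the 7 time points where every leaf had it well above background, its log2 ratio ran from -0.028 ± 0.18 at 17:00 to 4.56 ± 0.35 at 21:00 (SD, n = 8 each). The pseudo-response regulators OsPRR95 (Os09g0532400) and OsPRR1 (Os02g0618200) were 8.16- and 4.06-fold higher (log2 ratio 3.03 for OsPRR95, and 2.30 on another probe), and OsLHY (Os08g0157600), a morning Myb factor of the clock, was 7.07-fold lower and lower on 103 of 103 arrays. DTH2 (Os02g0724000), a CONSTANS-like flowering gene, and BAM3 (Os10g0565200), a beta-amylase of starch breakdown, were 3.51- and 5.92-fold lower.

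In total 760 genes passed limma's adjusted p threshold and a 2-fold change, 539 higher and 221 lower in osgi. Of the 14 circadian clock genes, 3 were called higher and 2 lower, OsLHY and OsGI. The clock list thus holds OsGI, the mutated gene itself, here and in its later counts. The other 9 clock genes passed the adjusted p but stayed under 2-fold, between -0.33 (OsELF4a (Os11g0621500)) and 0.78 (OsPRR59 (Os11g0157600), called at 1.07 under median centring) on the log2 scale. Of the 19 flowering time genes tested, DTH2 alone was called (log2 ratio -1.81 ± 0.036), but 13 passed the adjusted p on the lower side and 2 on the higher side. Those on the lower side included Ehd1 (Os10g0463400), an inducer of flowering (log2 ratio -0.52 ± 0.057), and the florigen gene Hd3a (Os06g0157700). Hd3a was well above background in only 45 Norin 8 and 23 osgi leaves, and in none at 3 and 5 of the 13 time points, so no value over the day is given, and it was called only with the processed signals and the series matrix values. The flowering list as a set was lower in osgi (camera adjusted p = 5.80e-04, and adjusted p = 0.00608 with an estimated correlation), and the clock list had no shift past the threshold (camera adjusted p = 0.836).

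Most listed genes of light harvesting, chlorophyll biosynthesis and the photosystems read higher in osgi, the majority by less than 2-fold. Of 12 light harvesting genes, 5 were called, all higher, and 10 passed the adjusted p on the higher side with 0 on the lower. LHCA1 (Os06g0320500), LHCA4 (Os08g0435900) and CAB1R (Os09g0346500), which encode chlorophyll-binding antenna proteins, were 2.56-, 2.54- and 2.46-fold higher, on 91, 81 and 85 of 103 arrays, although another CAB1R probe read 0.97 (log2) and was not called. Among 10 chlorophyll biosynthesis genes 9 passed the adjusted p on the higher side and PORA (Os04g0678700), a protochlorophyllide reductase, was called (2.38-fold higher, on 62 of 103 arrays). Of 11 photosystem subunits 10 passed the adjusted p on the higher side, led by PSAE (Os07g0435300) (log2 ratio 0.72 ± 0.042, and 1.31 under median centring, where it was called), and none reached 2-fold after loess. As sets these 3 lists were higher (camera adjusted p = 5.80e-04, 0.00262 and 0.0191), but each call was lost when the correlation between genes was estimated (adjusted p = 0.615, 0.615 and 0.863 with an estimated correlation). Of 13 Calvin cycle genes 8 passed the adjusted p on the higher side and 2 on the lower, none by 2-fold, with no shift of the set past the threshold (camera adjusted p = 0.389).

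Single members of other lists stood out. In starch and sucrose metabolism (2 of 17 called), BAM3 fell (log2 ratio -2.57 ± 0.053) and PHO1 (Os03g0758100), the plastidial starch phosphorylase, rose (1.52 ± 0.058). NADH-GOGAT2 (Os05g0555600), a glutamate synthase, was the 1 nitrogen assimilation gene of 11 called (1.39 ± 0.10, higher on 72 of 103 arrays), and NAP (Os03g0327800), a NAC factor of leaf senescence, the 1 of 5 senescence genes (lower, -1.19 ± 0.16). Of 14 abscisic acid and drought genes, SalT (Os01g0348900) rose (2.20 ± 0.15, 1.15 on another probe, well above background in 79 Norin 8 leaves) and DREB1A (Os09g0522200) fell (-1.24 ± 0.11, -0.78 and not called on another probe). GA2ox3 (Os01g0757200), a gibberellin-inactivating oxidase, rose (1.88 ± 0.092, 0.33 on another probe) as 1 of 7 gibberellin genes. PAL4 (Os04g0518400), CHS1 (Os11g0530600) and CHI (Os03g0819600) of phenylpropanoid and flavonoid synthesis rose (2.14 ± 0.17, 1.5 ± 0.29 and 1.21 ± 0.085) as 3 of 9, with 0.78 and no call on another CHS1 probe. Among 9 photoreceptors, 13 heat shock proteins, 12 phosphate starvation genes and 5 defence genes none was called, and limma's unadjusted p was below 0.05 for 6, 9, 9 and 2 of them. None of these 10 lists shifted as a set past the threshold (camera adjusted p from 0.120 to 0.890), but with all probes of a gene in the test the phosphate starvation list was called lower (camera adjusted p = 0.00267, against 0.120). The sign of the median member turned under median centring for nitrogen assimilation (-0.12 to 0.41), phenylpropanoid synthesis (-0.061 to 0.037), defence (-0.023 to 0.17) and the abscisic acid list (8.62e-04 to -0.18), and with the processed signals for gibberellin genes (0.017 to -0.075) and the abscisic acid list (-0.066), the last also without background subtraction (-0.0051). For photoreceptors, heat shock and abscisic acid genes the median was above 0 and the set test pointed down, and for phenylpropanoid genes the mean was 0.38 against a median of -0.061. Markers of other cells and organs were also read. All 6 dividing cell markers passed the adjusted p on the higher side (median log2 ratio 0.26, and 0.86 with the processed signals, camera adjusted p = 0.195), none by 2-fold. Among them Os01g0805600, Os04g0563700 and Os06g0726800 were well above background in no Norin 8 leaf at 2, 2 and 4 of the 13 time points. Their small ratios thus rest partly on dim signals. The 1 shoot meristem marker tested, OSH1 (Os03g0727000), was not called and was well above background in no Norin 8 leaf at 3 of the 13 time points. The 1 root marker, Lsi1 (Os02g0745100), read 0.27, and the 7 floral organ markers had a median of 0.095 (camera adjusted p = 0.654), which turned to -0.29 under median centring and read 0.23 with the processed signals. Of these floral markers OsMADS3 (Os01g0201700) and OsMADS58 (Os05g0203800) were well above background in no Norin 8 leaf at 6 and 7 time points, and OsMADS58 in no osgi leaf at 3. For every list the number called was equal when adjusted over the list alone.

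Outside the lists, the 6 genes highest in osgi included Os07g0131600, described as a monosaccharide transporter (57.5-fold, on 103 of 103 arrays, well above background in 87 Norin 8 leaves), and Os07g0529600, a thiazole biosynthetic enzyme (16.5-fold). Os12g0230100, an ATP-binding subunit of a Clp protease, was 59.6-fold higher in the mean, but its osgi leaves split into 2 separate levels. The lowest genes included Os01g0872900, of unknown function (10.8-fold lower, on 103 of 103 arrays), Os07g0131100, a protein kinase (7.38-fold lower), and Os04g0583900, a Myb protein. The last was well above background in only 45 osgi leaves, and in none at 4 of the 13 time points, so no fold over the day is given. Its log2 ratio ran from -1.15 ± 0.30 at the first 7:00 to -6.53 ± 0.24 at 1:00 (SD, n = 8 each) over the 4 time points where every leaf of both genotypes had it well above background. Since osgi RNA always carried Cy5, a constant dye bias of a probe cannot be told apart from genotype in the mean of any single probe. Among the 760 genes called in the mean, 64 pairs were neighbours in locus order, against a median of 22 in random draws. The labels do not give the origin of the mutant, so differences at other loci cannot be told apart from an effect of the OsGI mutation. The processed signals gave 1678 genes in place of 760. Median centring in place of loess gave 927 genes higher and 182 lower, and moved the median of all genes from 0.014 to 0.11 (log2).

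Taken hour by hour, the comparison asked when in the day the genotypes differed. Several clock genes differed most between 23:00 and 5:00. OsPRR95 was 114-fold higher in osgi at 23:00 (log2 ratio 6.83 ± 0.13 SE, n = 8 arrays, 6 of them with Norin 8 well above background, and 5.21 on another probe), and OsLHY 25-fold lower at 1:00. OsPRR1 and OsLUX (Os01g0971800), a Myb factor of the evening complex, were 9.90- and 7.62-fold higher at 5:00, where OsPRR1 was well above background in 2 of 8 Norin 8 leaves. At 17:00 DTH2 was 36.4-fold lower and Hd1 (Os06g0275000), the rice CONSTANS, 6.40-fold lower. Among antenna genes CAB1R was 19.5-fold higher at 19:00 and LHCA4 18.3-fold higher at 21:00.

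In all 5149 genes were called by limma at 1 time point or more. The number was lowest at 15:00 (934, 667 of them higher) and highest at 5:00 (2460, 1330 higher), where median centring gave 1962 higher and 806 lower, and at the first and second 7:00 it was 2016 (1492 higher) and 1463 (1082 higher). Median centring gave 2451 higher and 316 lower at the first 7:00, 1490 and 213 at 9:00, 1274 and 350 at 11:00, 1312 and 241 at 13:00, 851 and 379 at 19:00, 1213 and 415 at 21:00, 1179 and 371 at 23:00, 1199 and 332 at 1:00, 1351 and 558 at 3:00, and 2041 and 200 at the second 7:00. At 3:00 loess gave 945 and 707, and the processed signals 2409 and 852. Norin 8 stood apart at that hour, with a mean of 60.1% of probes well above background (52.2 to 56.1% on the slide of stages 3 and 4), against 71.1 to 77.6% at the other time points. At its hour of largest difference each of the 12 light harvesting genes was called, 11 of them higher, and so were 8 of 14 clock (6 higher), 8 of 19 flowering time (7 lower) and 8 of 10 chlorophyll biosynthesis genes (8 higher). PORA was 18.4-fold and GSA (Os08g0532200), an enzyme of the first steps of chlorophyll synthesis, 3.66-fold higher at 5:00, although another GSA probe read only 0.17 (log2). Of the flowering genes OsCOL4 (Os02g0610500) (log2 ratio -2.55 ± 0.24 at 5:00), Se5 (Os06g0603000) (-1.38 ± 0.10 at 1:00) and Ehd1 (-1.13 ± 0.21 at 11:00) were lower and DTH8 (Os08g0174500) (1.59 ± 0.14 at 5:00) higher. The call was lost for Ehd1 without st1_n1 (-0.97) or st3_n1 (-1.0), labels of a stage and plant, and for Se5 under median centring (-0.95). Calvin cycle genes (7 of 13) and photosystem subunits (6 of 11) were called on the higher side, among them GAPB (Os03g0129300) (2.09 ± 0.13 at 5:00) and PSAK (Os07g0148900) (1.65 ± 0.25 at 17:00). Starch and sucrose genes went both ways (6 higher and 5 lower of 17), with AGPL1 (Os05g0580000), a subunit of ADP-glucose pyrophosphorylase, 16.4-fold higher at 15:00 and BAM3 29.1-fold lower at 21:00.

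Nitrogen genes were split as well (3 higher and 4 lower of 11), with NADH-GOGAT2 21-fold higher at 23:00, where 6 of 8 Norin 8 leaves had it well above background, and the nitrate reductase gene NIA1a (Os08g0468100) 6.72-fold lower at 5:00 (log2 ratio -2.75, and -3.08 and -4.23 on its other 2 probes). In phosphate starvation (4 higher and 5 lower of 12) the sensor genes SPX1 (Os06g0603600) and SPX2 (Os02g0202200) were 4.09- and 3.77-fold higher at the first 7:00 and SPX-MFS2 (Os02g0678200) 5.46-fold lower at 5:00. Of the remaining lists, 7 of 9 phenylpropanoid, 6 of 13 heat shock, 4 of 5 senescence, 3 of 14 abscisic acid, 2 of 7 gibberellin, 2 of 5 defence, 2 of 6 dividing cell and 2 of 7 floral marker genes were called at their hour of largest difference. When adjusted over the list alone at each hour, 3 defence genes were called and the other counts were equal. None was among 9 photoreceptors and the root and meristem markers, with limma's unadjusted p below 0.05 for all 11 at that hour, which says little because the hour was chosen as the largest of 13. Outside the lists, large differences were those of Os09g0541000, a plasma membrane aquaporin (81.8-fold higher at 5:00, log2 ratio 6.35, and 5.56 on another probe), Os04g0675400, a DnaJ family protein (73.3-fold higher at 5:00), Os02g0685200, a Myb protein (71.0-fold lower at 1:00), and Os06g0298200, a CONSTANS-type zinc finger protein (45.3-fold lower at 17:00, log2 ratio -5.50, and -4.37 on another probe). Where the Norin 8 probe was not well above background on any array only a bound can be given, from normalized signals open to dye bias. At 3:00 and 5:00, where neither OsFKF1 probe was, the brightest of them was at least 18.3-fold and at least 23.4-fold higher in osgi (limma adjusted p = 4.97e-43 and 4.06e-46), the former at the hour when fewer Norin 8 probes were measured. At the first and second 7:00, where neither probe was above background in Norin 8 either, the bounds were lower, at least 11.95-fold and at least 10.08-fold. At 1:00 the other OsFKF1 probe, well above background in 3 of 8 Norin 8 leaves, read a log2 ratio of 5.22. Each time point had slides and a scan batch of its own, so time and batch cannot be told apart.

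**Figure D2:**
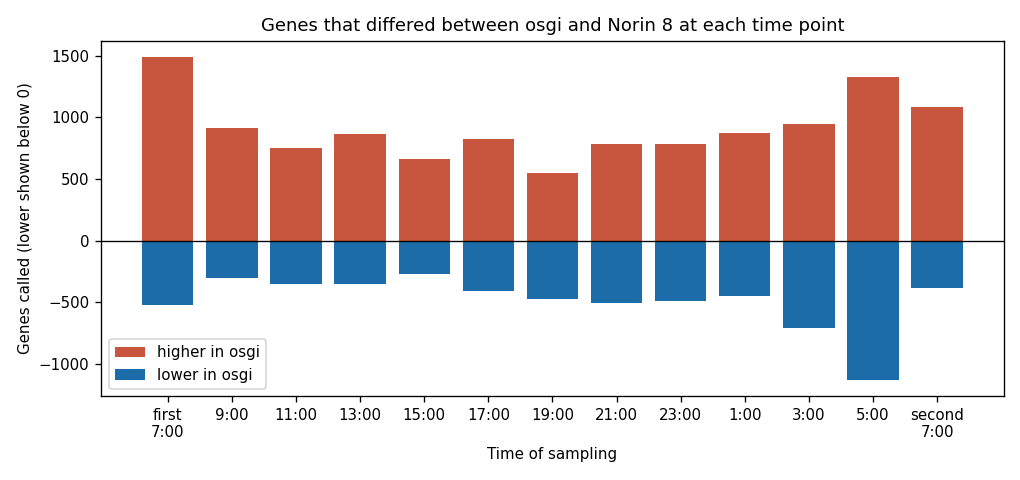
Number of genes called higher (above 0) and lower (below 0) in osgi than in Norin 8 at each of the 13 time points, by limma at an adjusted p under 0.05 and at least 2-fold, with 8 arrays each (7 at 19:00). The count was largest at 5:00, with 1330 higher and 1130 lower.

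The next test asked whether the osgi/Norin 8 ratio itself changed over the day, which a constant dye bias cannot produce. OsPRR95 moved over a range of 6.43 (log2), with its ratio highest at 23:00 and lowest at 15:00, OsLUX over 5.67 (highest at 5:00, lowest at 17:00) and OsLHY over 3.12. PORA ranged over 6.01, NADH-GOGAT2 over 6.04 and the antenna genes LHCA3 (Os02g0197600) and LHCB2 (Os03g0592500) over 4.62 and 4.53.

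The ratio varied by at least 2-fold for 6392 genes (limma F test over 103 arrays). They included 10 of 14 clock genes, 12 of 12 light harvesting, 9 of 10 chlorophyll biosynthesis, 15 of 17 starch and sucrose, 8 of 11 photosystem, 8 of 11 nitrogen, 9 of 12 phosphate starvation and 7 of 19 flowering time genes. Of 13 Calvin cycle genes 11 were called, and 12 when adjusted over the list alone, while for the other lists both counts were equal. Called as well were 4 of 9 photoreceptor, 7 of 13 heat shock, 6 of 14 abscisic acid, 4 of 5 senescence, 4 of 9 phenylpropanoid, 2 of 5 defence and 1 of 7 gibberellin genes, and 2 of 7 floral organ, 1 of 6 dividing cell and 1 of 1 root markers. DTH2 (5.36), OsCOL4 (3.37), Hd1 (3.34) and DTH8 (2.11) led the flowering genes by range, BAM3 (4.90) and AGPL1 (4.88) the starch genes, and SPX-MFS2 (3.26), SPX2 (3.26) and SPX1 (3.17) the phosphate genes. CAO1 (Os10g0567400), a chlorophyll b synthase, ranged over 2.81 and CHLH (Os03g0323200), a magnesium chelatase subunit, over 2.56. Large ranges outside the lists were those of Os04g0675400 (7.14), Os12g0189300, an isocitrate lyase family protein (6.60, highest at 17:00 and lowest at 5:00), and Os01g0175600, a bicarbonate transporter family protein (6.23). On another probe the range was 5.14 for OsPRR95, 3.78 for OsLHY, 4.66 for DTH2, 3.57 for LHCA3, 2.54 for SPX1 and 5.78 for Os12g0189300.

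Across the 4 stages few genes changed their ratio, and the question was whether plant age altered the difference between the genotypes. PORA was the only listed gene called, with a range of 1.58 (log2, limma adjusted p = 0.0104), and its call was lost without st1_n1 (1.38) or st4_n2 (1.26), labels of a stage and plant. Os12g0458100, a transferase family protein, ranged over 2.58 but was well above background in only 27 Norin 8 leaves and in none at 11:00, Os01g0106400, an isoflavone reductase-like protein, over 2.44, and Os01g0825800, an amino acid transporter, over 1.74.

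In all the ratio of 41 genes varied between stages by at least 2-fold (limma F test). When adjusted over the list alone, 1 flowering time gene and 1 defence gene were also called. In the 19 lists with no call, limma's unadjusted p was below 0.05 for 35 of 186 members. The total was 23 genes without st1_n1, 64 without st1_n2, 22 without st4_n1 and 23 without st4_n2.

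In Norin 8 leaves the clock genes ran through large daily cycles. OsPRR95 had a peak to trough of 8.87 ± 0.29 (log2, SE, n = 103) with its peak at 12.6 h, OsLUX of 8.38 ± 0.28 at 19.1 h and OsLHY of 8.00 ± 0.12 at 6.36 h. The antenna gene CAB1R cycled by 8.95 ± 0.32 with a peak at 11.7 h, and BAM3 by 8.01 ± 0.24 with a peak at 0.872 h.

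By a cosine of 24 h, 8297 genes were rhythmic in Norin 8 (limma F test, peak to trough of at least 1). The F tests and SEs of all 3 rhythm comparisons took arrays as independent, although those of one hour shared 1 scan batch. With whole time points in a random order up to 5309 genes were still called in Norin 8. The adjusted p is therefore no error rate for a 24 h cycle. All 12 light harvesting genes were called, 12 of 14 clock, 9 of 10 chlorophyll biosynthesis, 13 of 17 starch and sucrose, 10 of 19 flowering time, 7 of 9 photoreceptor, 8 of 11 nitrogen and 9 of 13 heat shock genes. Called as well were 5 of 13 Calvin cycle, 2 of 11 photosystem, 4 of 5 senescence, 5 of 14 abscisic acid, 7 of 12 phosphate starvation, 5 of 7 gibberellin, 6 of 9 phenylpropanoid and 1 of 5 defence genes and 2 of 7 floral organ markers. Of the 8 dividing cell, meristem and root markers none was called, with limma's unadjusted p below 0.05 for 6. Counts adjusted over the list alone were equal in all 3 rhythm tests. DTH2 and Hd1 peaked at 22.7 and 22.1 h with a peak to trough of 6.11 and 4.72, PHYB (Os03g0309200), a phytochrome, at 20.9 h (2.00), PORA at 14.2 h (6.73), HsfA2d (Os03g0161900), a heat shock factor, at 9.33 h (4.96) and DREB1A at 23.9 h (5.00). RCA (Os11g0707000), the Rubisco activase gene, peaked at 5.73 h (2.78). Outside the lists the Myb gene Os02g0685200 cycled by 9.95 (peak at 3.52 h). On another probe the peak to trough was 7.22 for OsPRR95, 11.09 for CAB1R, 1.19 for PHYB, 1.39 for RCA and 4.31 for DREB1A.

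In osgi leaves many of these genes still cycled. OsLHY did so by 7.03 ± 0.10 (log2, SE, n = 103) and OsGI by 5.67 ± 0.13, while OsPRR95 cycled by 2.36 ± 0.11, OsPRR1 by 2.62 ± 0.054 and OsFKF1 by 2.97 ± 0.13. The antenna genes LHCB2 and CAB1R cycled by 6.50 ± 0.37 and 6.24 ± 0.36 with peaks at 13.3 and 13.0 h. An early light-inducible protein gene, Os07g0178700, cycled by 10.66 ± 0.33 (peak at 11.9 h).

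The cosine test called 5825 genes in osgi, and up to 3610 with whole time points in a random order. The 5825 genes included 11 of 14 clock, 11 of 12 light harvesting, 7 of 10 chlorophyll biosynthesis, 13 of 17 starch and sucrose, 9 of 19 flowering time, 5 of 11 nitrogen, 3 of 9 photoreceptor and 8 of 13 heat shock genes. In the Calvin cycle RCA was the 1 gene of 13 called (2.14, peak at 6.75 h, 0.26 on another probe). Called as well were 3 of 5 senescence, 5 of 14 abscisic acid, 7 of 12 phosphate starvation, 4 of 7 gibberellin, 5 of 9 phenylpropanoid and 2 of 5 defence genes and 2 of 7 floral organ markers. None was called of 11 photosystem subunits and the dividing cell, meristem and root markers, where limma's unadjusted p was below 0.05 for 17 of 19 members. PHOT1a (Os12g0101800), a blue-light receptor, cycled by 2.55 with a peak at 2.13 h, and Os05g0586600, the plastid sigma factor SIG5, by 7.16 (peak at 9.40 h). Another probe gave 4.41 for Os05g0586600, 7.85 for LHCB2 and 9.69 for CAB1R. Both genotypes shared 5000 rhythmic genes, against 1877 for independent lists of these sizes, although both channels come from the same arrays.

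A direct test of the difference asked whether the rhythms themselves were altered. Over the 6708 genes with a clear rhythm the median amplitude in osgi was 77.3% of that in Norin 8 (log2 ratio -0.37, mean over the 8 plant labels -0.37 ± 0.050 SD, n = 8), and the median peak came 0.910 h later (0.917 ± 0.088 h SD, n = 8). Plant labels do not pair leaves across hours, and all 8 share the scan batches, so this SD leaves out batch effects. The 12 light harvesting genes peaked a median of 1.75 h later, each of them later and with a lower amplitude. The rhythm of the ratio had a peak to trough of 6.81 ± 0.27 (log2, SE) for OsPRR95, 3.65 ± 0.29 for OsLUX and 1.52 ± 0.11 for OsGI. Another OsPRR95 probe gave 5.37, and another OsGI probe, dim in osgi at 3:00 and 5:00, gave 3.59.

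The rhythm differed for 3423 genes (limma F test), and for up to 2057 with whole time points in a random order. Among the 3423 were 12 of 12 light harvesting, 10 of 14 clock, 8 of 10 chlorophyll biosynthesis, 9 of 17 starch and sucrose, 6 of 11 nitrogen, 7 of 9 phenylpropanoid, 5 of 19 flowering time, 4 of 9 photoreceptor and 4 of 5 senescence genes. Also called were 4 of 13 Calvin cycle, 2 of 11 photosystem, 3 of 13 heat shock, 4 of 12 phosphate starvation, 1 of 14 abscisic acid, 1 of 7 gibberellin and 1 of 5 defence genes and 1 of 7 floral markers, and of the 8 other markers none, with limma's unadjusted p below 0.05 for 5. DTH2 (4.60 ± 0.21) and Hd1 (2.77 ± 0.14) led the flowering genes, BAM3 (4.41 ± 0.24) and AGPL1 (4.11 ± 0.33) the starch genes, and NADH-GOGAT2 (4.71 ± 0.35) and PORA (5.93 ± 0.47) their lists. Outside the lists Os07g0147500, a photosystem II polypeptide (6.19 ± 0.60), was among those with a large difference. By list the median amplitude in osgi was 69.7% of that in Norin 8 for 12 clock genes, 71.6% for light harvesting and 59.0% for 8 chlorophyll biosynthesis genes, and the median delay was 2.25 h for 7 nitrogen genes and 1.81 h for 12 starch and sucrose genes. The median amplitude was hardly lower for 6 phosphate starvation (97.3%), 4 gibberellin (99.6%) and 6 phenylpropanoid genes (99.8%). Of 9 photoreceptor genes 4 had a clear rhythm, with a median amplitude of 142%, and 50% of these 4 had a lower amplitude in osgi.

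**Figure D3:**
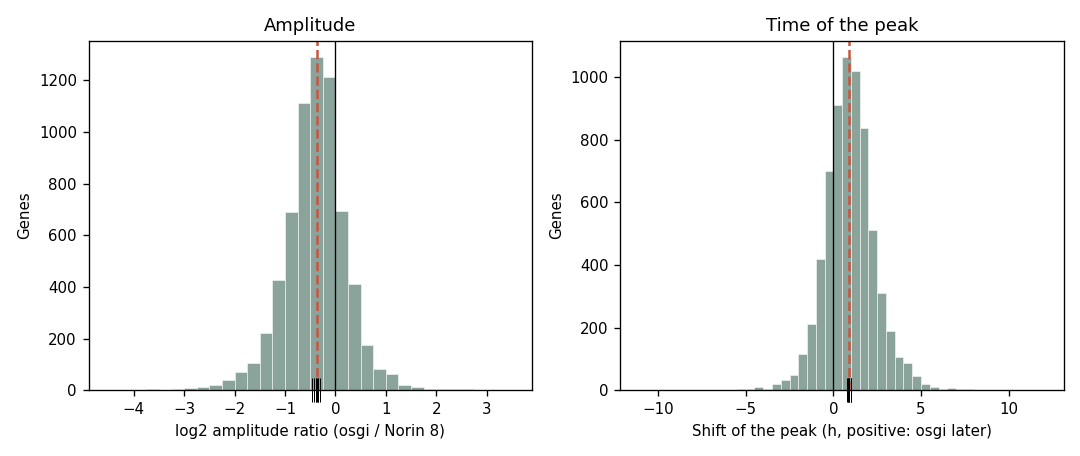
Left, distribution of the log2 ratio of the 24 h amplitude in osgi over that in Norin 8 for 6708 rhythmic genes. Right, distribution of the shift of the peak in hours (positive when osgi is later). Dashed lines mark the medians, -0.37 and 0.910 h, and the ticks on the axis the medians of the 8 plant labels.

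Plant age was compared within each genotype. In Norin 8 the senescence factor NAP was higher in stage 1, the earliest transplanted, than in stage 4 (log2 difference 1.39 ± 0.30 SE). PORA (-1.50 ± 0.29), the antenna gene LHCB1.3 (Os01g0720500) (-1.60 ± 0.33) and the flavonoid genes CHS1 (-1.32 ± 0.52), PAL4 (-1.23 ± 0.36) and CHI (-1.04 ± 0.20) were lower in stage 1, as was SalT (-1.10 ± 0.23, -0.65 and not called on another probe).

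In all 373 genes differed by limma, 150 higher and 223 lower in stage 1. The 15 lists with no call had 66 of 146 members past limma's adjusted p, none with 2-fold, and 70 past an unadjusted p of 0.05, and counts adjusted over the list alone were equal. By adjusted p alone, 8 of 12 light harvesting genes (LHCB1.3 among them) and 9 of 17 starch and sucrose genes were lower in stage 1. Without st4_n2 the differences of CHS1, PAL4, CHI and SalT were -1.01, -0.93, -0.87 and -0.97, without st1_n1 those of CHS1, CHI and SalT -1.25, -0.95 and -0.96, without st1_n2 that of CHS1 -1.41 and without 3:00 that of CHI -0.97, none of them called. Large changes were those of Os10g0456100, a Brn1-like protein (2.28 ± 0.31), and Os11g0691500, a protein kinase (2.11 ± 0.18), both higher in stage 1, and of Os06g0141200, an RNA-binding protein (-2.48 ± 0.32), and Os05g0548900, a phosphoethanolamine methyltransferase (-2.45 ± 0.21), both lower. Stages 1 and 4 lay on different slides. Within slides, 8 genes were called between stages 1 and 2 and 9 between stages 3 and 4, across slides 0 between stages 2 and 3 (limma, 3617 genes at an unadjusted p under 0.05), and with slide as a random block 370 genes were called between stages 1 and 4. Loess without scaling between arrays gave 244 higher and 145 lower.

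In osgi OsMADS14 (Os03g0752800), a MADS-box gene of the floral transition, was 4.60-fold higher in stage 1 than in stage 4 (log2 difference 2.20 ± 0.27 SE), but another of its probes read 0.73 and was not called. PT2 (Os03g0150800), a phosphate transporter, was higher (1.02 ± 0.12, 0.12 on another probe), and PR1b (Os01g0382000), a pathogenesis-related gene (-1.82 ± 0.35), LHCB1.3 (-1.33 ± 0.43) and the root marker Lsi1 (-1.09 ± 0.14) were lower in stage 1.

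In all 265 genes differed by limma, 123 higher and 142 lower in stage 1. In the 15 lists with no call 50 of 147 members passed limma's adjusted p and 66 the unadjusted p of 0.05, and counts adjusted over the list alone were equal. Os11g0691500 was again high in stage 1 (2.68 ± 0.20), and Os09g0538000, an RNase S-like protein (-3.63 ± 0.45, -1.87 on another probe), Os12g0247700, a beta-glucosidase aggregating factor (-2.93 ± 0.49), and Os05g0548900 (-2.79 ± 0.27) were low. Os11g0540600 (1.72 ± 0.64) is one of the genes whose osgi leaves fall into 2 levels, and its call was lost without st1_n1 (1.63), st1_n2 (1.77), st4_n1 (1.45), 13:00 (1.33) or 3:00 (1.52). Likewise PT2 was not called without st1_n2 (0.94) or st4_n2 (0.91), nor Lsi1 without st4_n2 (-0.95). Both genotypes shared 139 called genes, each with the same direction in both, against 0.716 higher and 1.23 lower genes for independent lists, and both were read on the same arrays. Within slides, 2 genes were called between stages 1 and 2 and 4 between stages 3 and 4, while across slides 24 were called between stages 2 and 3 (3 higher and 21 lower in stage 2). With slide as a random block 262 were called between stages 1 and 4, and loess without scaling between arrays gave 227 higher and 91 lower.

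The last comparison set the second 7:00 against the first in Norin 8, which shows how far the same hour repeated on the next day. Os01g0210900, a cytochrome P450 (log2 difference -2.59 ± 0.21 SE, n = 8 arrays each), Os06g0256500, a cytosolic glucose-6-phosphate isomerase (-2.19 ± 0.18, -0.90 and not called on another probe), and Os07g0529600, the thiazole enzyme (-2.13 ± 0.13), were lower on the second morning. Os11g0640600, a disease resistance protein (1.46 ± 0.12), and Os02g0758000, a small heat shock protein (1.41 ± 0.27), were higher.

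In 206 genes the mornings differed by limma, 40 higher and 166 lower on the second. No member of the 20 gene lists was called, also when adjusted over the list alone, while 45 of 196 members passed limma's adjusted p and 57 the unadjusted p of 0.05. They included 6 flowering time genes on the higher side and 5 starch and sucrose genes on the lower by adjusted p. Os10g0147400, an auxin carrier-like protein, rose by 1.99 ± 0.13 on its brightest probe, but its other 2 probes read -0.17 and -0.16. The mornings lay on different slides and scan batches, which cannot be told apart from the day, and loess without scaling between arrays gave 19 higher and 342 lower.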

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

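The tests of the brightest rhythmic genes, of a later cutting time and of steady ratios around midday were chosen only after the result was seen.

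Spike-in transcripts of known ratio read too small a ratio around midday. The mean slope of observed on known log ratios was 0.483 at 11:00 and 0.123 at 13:00 (8 arrays each), against at least 0.828 at every other time point. At 11:00 the array st2_n2 had a slope of 0.305, apart from the nearest at 0.478, and the array st4_n2 had 72.8% of Norin 8 probes (nearest 77.7%) and 72.2% of osgi probes (nearest 80.5%) well above background. At 19:00 the array st2_n1 had a slope of 0.919 (nearest 0.904, 7 arrays). Of 54 sets of values examined 4 held such a single array, and chance gives about 1 in 20. Leaf transcripts did not lose their ratios to that extent. Over 134 genes with a steady ratio of at least 2-fold, chosen without the hours from 9:00 to 15:00, the slope on the mean of the first 7:00 and 17:00 was 1.01 at 9:00, 0.969 at 11:00, 0.912 at 13:00 and 0.930 at 15:00.

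On the array left out, whose osgi channel the submitters did not use, OsGI read -3.45 (log2 ratio), beyond the -3.05 to -2.74 of the other 7 arrays at 19:00. Its ratios correlated with the mean of those arrays by 0.281 across genes, against 0.638 to 0.841 for each of them.

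The difference between the genotypes changed with the hour for 6392 genes, with the stage for 41 and in its daily rhythm for 3423, each by a test of the difference itself. In each of 10 comparisons 1 of 100 splits of the arrays, the real one, gave as many genes. This argues against a chance split for the counts as a whole, but not for single genes, since some other splits also called many. Splits that moved single arrays broke up the slides and scan batches, so they do not test a batch effect. With the sign of M turned on random arrays, the highest of the other splits gave 13 genes against 760 in the mean and 2512 against 5149 at single hours. With arrays moved between time points it was 376 against 6392, and with arrays moved between stages it was 9 against 41 for the ratio and 0 against 373 in Norin 8 and 0 against 265 in osgi. With whole time points in a random order it was 5309 against 8297 rhythmic genes in Norin 8, 3610 against 5825 in osgi and 2057 against 3423 for the difference, and with arrays moved between the mornings 51 against 206. For the gene lists chance is not excluded, since 16 of 100 splits called as many as the 4 lists of the real one, and the highest other 6.

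Rhythms in osgi had a lower amplitude (median log2 ratio -0.37) and a later peak (0.910 h). An evenly compressed Cy5 channel as the whole cause is argued against by the stage differences of 260 genes. They were compressed by only -0.097 (log2, 95% bootstrap interval over genes -0.17 to -0.027), which leaves a part of that size open. This takes the stage response to be alike in both genotypes, which was not tested. Compression that grows with the size of a change also stays open, since the largest rhythms exceed the stage differences. Cy5 background on dim probes is argued against by the brightest 2236 genes, whose median ratio was -0.45 (95% bootstrap interval over genes -0.47 to -0.41). Both bootstrap intervals leave out the spread between arrays and scan batches. One later cutting time for all osgi leaves is argued against by 381 strong rhythms, of which 61.7% had a 95% interval that excluded their median shift of 1.26 h (5th to 95th percentile -0.05 to 2.94 h). These intervals took the arrays as independent and each rhythm as a pure cosine, so they can be too narrow and the share too high. An altered clock in osgi, a biological difference the design names, stays open and was not tested here.

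Genes called in the mean over the day could carry a constant dye bias, since osgi RNA was always Cy5. Of 496 other probes of 271 called genes 98.6% had the same sign, against 86.3% for genes not called, which argues against a bias of single probes as the cause of the direction for these genes as a set, but only 71.6% were also past 2-fold that way, so for the size of single genes it stays open. Probes of one gene can overlap and share a bias, and called genes with a single probe were not covered. For such genes genotype and dye remain open.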

How the results depend on the processing

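The settings with an offset of 1 and those without 13:00, without 11:00 and 13:00, or without 3:00, were chosen only after the result was seen. Over all settings run, 239 summary values stayed within 1.5 times of the reported count (or the spread of the plant labels) and 37 moved. Agilent's processed signals gave more genes in every comparison, 1678 in the mean, 9933 at single hours, 11526 across hours, 101 across stages, 12897, 10059 and 5846 for the rhythms of Norin 8, osgi and the difference, 1077 and 810 between stages in Norin 8 and osgi, and 909 between mornings. The series matrix values gave 1676, 9932, 11501 and 100 for the first 4 of these. A 1.5-fold threshold, lower by construction, gave 2418, 11014, 12372, 163, 14230, 11752, 7853, 1427, 1114 and 1344 in the same order. An F test over time points, which also takes patterns other than a cosine, gave 12713 rhythmic genes in Norin 8 and 9995 in osgi. An offset of 1 gave 644 and 451 genes between stages and 419 between mornings, and loess without scaling between arrays 361 between mornings. Without 11:00 and 13:00 the median shift of the peak was 1.00 h. Over the settings the amplitude ratio ran from -0.35 to -0.39 (log2) and the shift from 0.870 to 1.00 h. Of 18 lists, 4 were called as reported, 1 with an estimated correlation, 5 with all probes of a gene (phosphate starvation the one gained, adjusted p = 0.00267) and 13 by fry, which asks another question. Except where the setting itself shows it, the cause was not tested.

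Leaving out 1 plant label gave 22 to 64 genes across stages (23 without st1_n1, 64 without st1_n2, 22 without st4_n1, 23 without st4_n2), and no other count moved by over 1.5 times. Of the counts at single hours 252 stayed and 43 moved, all of them upward, 13 of 13 with the processed signals (2029 to 4062), the series matrix values and the 1.5-fold threshold, 3 with an offset of 1 and 1 under median centring. Of the values of named genes 3375 stayed on their side of the threshold, 36 lost the call, 6 gained it and 1 reversed, Os10g0147400 between the mornings, at -0.17 on another probe (cause not tested). Of 140 called 139 were also called with the processed signals in the same direction, and for 51 of 52 with other probes and a direction all of these had the same sign. Of values for single lists 41 stayed, 3 lost and 10 gained the call.

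Plant labels do not pair arrays across hours. Arrays of the same label had a median correlation of their deviations of -0.037 in M, -0.027 in Norin 8 and -0.010 in osgi over 612 pairs, of which 34.3, 34.0 and 37.7% exceeded 0.1, and 13, 5 and 12 of 103 arrays correlated best with their own of 8 labels. With the label as a replicate block the counts were 760, 5148, 6400, 41, 8299, 5831, 3429, 377, 269 and 207, in the order above, and it changed no call of a named gene. With slide as a random block (correlation over 3000 probes, with time points in the fit, 0.042 in M, 0.099 in Norin 8 and 0.149 in osgi, and with a cosine 0.148, 0.407 and 0.385) they were 759, 5129, 6200, 37, 8247, 5736, 3381, 370, 262 and 191.

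Signal over background limits dim probes. Leaving out the subtraction moved M by a median of only 0.0052 (90th percentile 0.054), because the offset of 50 lies near the median backgrounds of 45.3 and 52.5, so that this setting tests little, while an offset of 1 moved it by 0.029 (0.30).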

Other observations

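All tests of the genes at 2 levels in osgi leaves were chosen only after the result was seen.

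The 8297 rhythmic genes of Norin 8 peaked most often between 16 and 18 h (992 genes), while among the 5825 of osgi, another set of genes, 743 peaked between 10 and 12 h, 728 between 0 and 2 h and 707 between 22 and 24 h, so that the tallies give no shift of a gene's peak. Over all 6708 genes with a clear rhythm 76.5% peaked later in osgi (median shift 0.910 h), and no test set a list against the other genes. The median shift was 2.86 h for the 6 of 9 phenylpropanoid and flavonoid genes with a clear rhythm, 2.57 h for 4 of 5 senescence genes, 1.89 h for 6 of 12 phosphate starvation genes and 1.05 h for 8 of 13 heat shock genes, each of these genes later than in Norin 8. It was -0.045 h for 4 of 14 abscisic acid and drought genes and 0.433 h for 4 of 7 gibberellin genes, with 50% of them later in each.

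In osgi leaves some transcripts took 2 separate levels from leaf to leaf. A gene counted as such if a gap of at least 2 (log2) within the middle 80% of its leaves parted them, with leaves on both sides at 7 or more time points. This rule found 20 genes in osgi and 0 in Norin 8, all 20 called in the mean over the day. On simulated data of 10000 genes, with noise independent between arrays, it found 78.5% of 200 genes at 2 levels with 0 false calls. The simulated levels lay at a single fixed distance, wider than the gap the rule asks for, so 78.5% holds for that distance only. The unchanged genes carried plain normal noise, in which such a gap hardly arises, so the 0 false calls say little. Os12g0230100, the Clp protease subunit, was at 14.3 (log2) or above in 76 of 103 osgi leaves (73.8%, exact 95% interval 64.2 to 82.0%) and at 10.07 or below in the rest. Other such genes were Os11g0639600, Os11g0606400 and Os11g0229500, described as disease resistance proteins, and Os12g0628500, a methionine aminopeptidase-like protein, all chosen after their values were seen.

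Norin 8 RNA in the osgi channel of some arrays is argued against by OsGI, which was lower in osgi by at least 0.74 (log2) on each of 103 arrays. Failed spots are argued against for Os12g0628500, Os11g0539600 and Os11g0235700 alone. There Norin 8 lay a median of 4.60 (log2) above the top of the low osgi level. The Cy3 residual SD of the same spots was only 0.0823 times that of Cy5 (0.0675 to 0.0908). For the other 17 genes failed spots stay open. Their Norin 8 lay a median of only 0.069 above that level (-2.29 for Os12g0230100 to 1.04), so that a lost spot would hardly show in Cy3 (median ratio 0.196). Of these genes, Os12g0230100, Os12g0228500, Os12g0221600, Os12g0169300, Os12g0218300, Os11g0606400 and Os11g0618700 each had 27 low and 76 high leaves. Over the 17 genes 22 to 31 leaves were low, and whether these were the same leaves was not compared. A candidate explanation is that chromosome segments of another parent segregate among the osgi plants, for which 3 counts were tried. The first, over genes called in the mean, does not test segregation, because such genes need not differ between osgi leaves. Among the 760 genes called in the mean, 64 pairs were neighbours in locus order (45 with different descriptions) against a median of 22 and a highest of 41 in 1000 random draws (permutation p = 0.001, the smallest these draws can give), among the 20 genes 0 pairs were, which decides nothing because random draws also had a median of 0 (highest 2, p = 1), and 51 pairs of the 20 genes shared a chromosome, as the locus names give it, against a median of 17 in 10000 draws (highest 60, permutation p = 3.00e-04), with 8 genes on chromosome 11 and 7 on chromosome 12. Genes that cluster for another reason, such as resistance gene families, stay open, and the labels do not give the origin of the mutant.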
